A study of Mus musculus with 4 samples.

How the data were processed

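Total RNA from sorted hair follicle stem cells of back skin was extracted with Trizol, and biotin-labelled cRNA was made from 2 µg of it and hybridised to Affymetrix arrays, per the labels' protocols. The deposited table holds intensity values on a linear scale for 22690 probe sets on 4 arrays. RMA, which corrects background, normalises between arrays and summarises probes into probe sets, is named in the submitters' processing notes, and its version and settings are not given in the sources used here. RMA usually writes log2 values, but the deposited intensity values ran from 5.29 to 25561 with near-equal medians of 82.0 to 83.3, so they were taken as linear and log2 was computed from them. RMA gives no detection call, so weak signal was judged by level alone, and fold values of genes near the lowest intensities are compressed. No scanner files were used here, and no slide or scan date was at hand to serve as a batch.

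Probe sets were named from the platform annotation. Of the probe sets, 20380 had 1 gene symbol, 691 had several, 1555 had none and 64 were controls, and only those with 1 symbol were named or tested. Gene identifiers of 20351 of them were found in a RefSeq gene table of the mouse assembly GRCm38.p6, and 0 symbols changed. That table served only for names and for which genes neighbour each other. The files name no genome build, so no coordinates are given. Each of the 12393 genes was represented by its probe set with the highest mean over the 4 arrays. Genes whose mean lay below percentile 40 of all probe sets (log2 5.40, linear 42.2) were left out, as were Xist and Y-linked genes, which served only to check the sex label. This left 8032 genes. Of 101 genes listed for the text, 42 had several probe sets, and 1, Runx1, had a second probe set above the limit with the opposite sign. Another 8 had a further probe set above the limit that differed by less than 1.5-fold where the chosen one differed by more.

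Samples were grouped by the genotype in their titles, and by the set number, in 2 comparisons: cKO against WT, and set 2 against set 1. Each was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, all 4 arrays, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. Tbx1 was tested among all probe sets whatever its level. Counts of genes that differed at least 1.5-fold in the same direction within both pairs carry no test, and stand beside the count in opposite directions. 27 gene lists were fixed before the data were examined, as were the tests of both comparisons, the rule for named genes and all alternatives but 4. Tests of explanations were written later, some of them after the results were seen. The 23 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. camera compares a list with all other genes. With an estimated correlation no list was called in either comparison, but that test rests on the 2 residual degrees of freedom of the fit and has little power. fry, which asks whether the genes of a list move one way and makes no comparison with other genes, called no list between genotypes and 1, Hedgehog, between sets (adjusted p = 0.0251). Named genes were Tbx1, the 12 genes per direction and comparison that passed the threshold or, where fewer passed, had the largest smaller within-pair difference, and up to 4 members per list with the largest mean difference. Some list members within this rule are not named, a choice made after their values were seen.

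The titles give one cKO and one WT array the same set number, and the descriptions give both arrays of a set the same state. The set was therefore read as pairing the arrays, and the model with the set as a block was an alternative. Across genes, deviations of the same-numbered arrays from their group means correlated with r = 0.192. The blocked value stands beside a result where it changed a call.

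The models were tested on simulated data with the residual spread of these 8032 genes, 200 changed genes per draw and 20 draws. Without the block, limma recovered 33.0% of genes changed by 1 on the log2 scale, 94.1% at 2, 99.6% at 4 and 100% at 6, and a mean of 4.66% of calls were false (1.25% to 9.14%). With the set as a block it recovered 70.4% at 1 and 99.3% at 2, and a mean of 10.5% of calls were false (1.88% to 19.6%). camera recovered a mitosis list shifted by -0.6 in all 20 draws and called 1 of 440 unshifted lists. The simulated genes were independent of each other, so these draws do not test camera's preset correlation. In the genotype comparison the estimated correlation was 0.08 for mitosis genes and 0.77 for interferon genes.

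Alternatives were no filter on dim genes, a filter at percentile 60, the mean of a gene's probe sets, each probe set on its own, a second quantile normalisation, centring each array on its median, a variance trend with robust fitting, a threshold of 0.10, a minimum of 2-fold, the blocks, an estimated correlation, fry, and each array left out in turn. A fit without 1 array leaves 1 sample in an arm, which is assumed to vary like the other group. The comparison of the cKO set 2 and WT set 1 arrays alone was chosen after seeing the data, as were 3 other filters on the separate list of endothelial markers (none, the mean level at or above the dim limit, and every array at or above it). Intervals of medians are bootstrap intervals over genes (95%, 2000 draws), and cover the choice of genes and not the spread between arrays.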

Results

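Hair follicle stem cells were purified by fluorescence-activated cell sorting from the back skin of female mice of mixed CD1 and C57BL/6 background at about postnatal day 60, and their RNA was measured on 4 Affymetrix arrays. The sort used yellow fluorescent protein (YFP), integrin α6 and CD34, a combination that marks cells of the bulge, the stem cell niche of the resting hair follicle. Cells came from 2 groups of 2 arrays each: wild type (WT) mice and conditional knockouts (cKO) of Tbx1, which encodes a T-box transcription factor. One cKO and one WT array were numbered together as a set, giving 2 sets. The treatment text describes wax depilation 48 h before harvest for all 4 samples, whereas a second label calls both samples of set 1 quiescent and both samples of set 2 activated. The labels do not settle this difference, and the sets are therefore named by number. Each array carried 22690 probe sets, and the median log2 intensity lay between 6.36 and 6.38 on all 4. With 2 arrays per group, an exact permutation test of a single value cannot give a p below 0.333, and the number of arrays limits the precision of every value here. Nothing in the labels says that the arrays of a group came from separate animals. limma's p-values for genes therefore measure only the spread between these samples, which may be technical. camera's p-values for lists at the preset correlation measure the spread across genes instead, and do not show that a shift would recur in other samples.

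Tbx1 itself was lower on both cKO arrays than on both WT arrays. Its single probe set read 9.54 and 8.88 in cKO and 10.53 and 10.37 in WT on the log2 scale, with means of 9.21 ± 0.46 and 10.45 ± 0.11 (SD, n = 2). The difference of -1.24 (SE 0.25) put the cKO signal at 42.4% of WT, at 50.3% within set 1 and 35.7% within set 2. This difference did not pass limma's test over all probe sets (adjusted p = 0.336). Whether the probe set lies inside the deleted part of the gene is not given in the sources used here, so the remaining signal is no measure of how completely the gene was deleted.

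The comparison of cKO with WT asked which transcripts differ in sorted stem cells when Tbx1 is removed. Of 8032 genes tested with limma, 7 passed at an adjusted p under 0.05, and 5 of these were lower in cKO. Fabp4, a fatty acid carrier of fat cells and capillary endothelium, fell by 6.55 on the log2 scale (SE 0.27, adjusted p = 0.00305). Aqp1, a water channel, fell by 4.55 (SE 0.29, adjusted p = 0.00781). Selp, the adhesion receptor P-selectin of endothelium and platelets, fell by 4.24 (SE 0.20, adjusted p = 0.00408). Plvap, a component of endothelial fenestrae, fell by 3.79 (SE 0.21), and Srgn, the proteoglycan serglycin, fell by 2.79 (SE 0.16), both with a limma adjusted p of 0.00652. WT levels of these 5 genes ran from 7.49 ± 0.09 for Srgn to 10.28 ± 0.21 for Fabp4 (SD, n = 2). On both cKO arrays all 5 lay below the limit used for dim genes, a log2 intensity of 5.40. Set against that limit in place of the measured cKO level, Fabp4 was at least 29.5-fold lower in cKO and Srgn at least 4.26-fold lower.

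The genes that rose in cKO were Cck and Tsc22d3. Cck, which encodes the peptide hormone cholecystokinin, rose by 2.30 (SE 0.17, limma adjusted p = 0.0189), from 4.91 ± 0.20 in WT to 7.21 ± 0.05 in cKO (SD, n = 2). Both WT arrays lay below the dim limit, and set against that limit Cck was at least 3.51-fold higher in cKO. Tsc22d3, a glucocorticoid-induced leucine zipper gene, rose by 1.80 (SE 0.17, limma adjusted p = 0.0479), from 8.60 ± 0.0025 to 10.40 ± 0.16, while its other probe sets read 1.92 and 0.40. Tsc22d3 lost its call without the filter on dim genes (adjusted p = 0.0595), at the percentile 60 filter (0.104) and with the mean of its probe sets (difference 1.37, adjusted p = 0.0784). With each array left out in turn, which leaves fewer samples for the fit, the differences of these 7 genes moved little and several calls were lost. The differences ran from -6.90 to -6.21 for Fabp4, -4.96 to -4.13 for Aqp1, -4.47 to -4.01 for Selp, -4.05 to -3.54 for Plvap, -2.86 to -2.71 for Srgn, 2.16 to 2.44 for Cck and 1.69 to 1.91 for Tsc22d3. limma called 2 genes without the WT set 2 array and 16 without the cKO set 2 array. Tsc22d3 lost its call whichever array was left out (limma adjusted p from 0.0737 to 0.244). Cck kept its call only without the cKO set 2 array and otherwise reached 0.0555 without the WT set 1 array, 0.0833 without the cKO set 1 array and 0.155 without the WT set 2 array. Without the WT set 2 array only Aqp1 and Plvap stayed below the threshold, and limma's adjusted p was 0.0691 for Fabp4 (difference -6.41) and 0.0752 for Selp (-4.24) and Srgn (-2.85). Without the WT set 1 array the adjusted p was 0.0526 for Selp (-4.24) and 0.0529 for Srgn (-2.72).

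**Figure D1:**
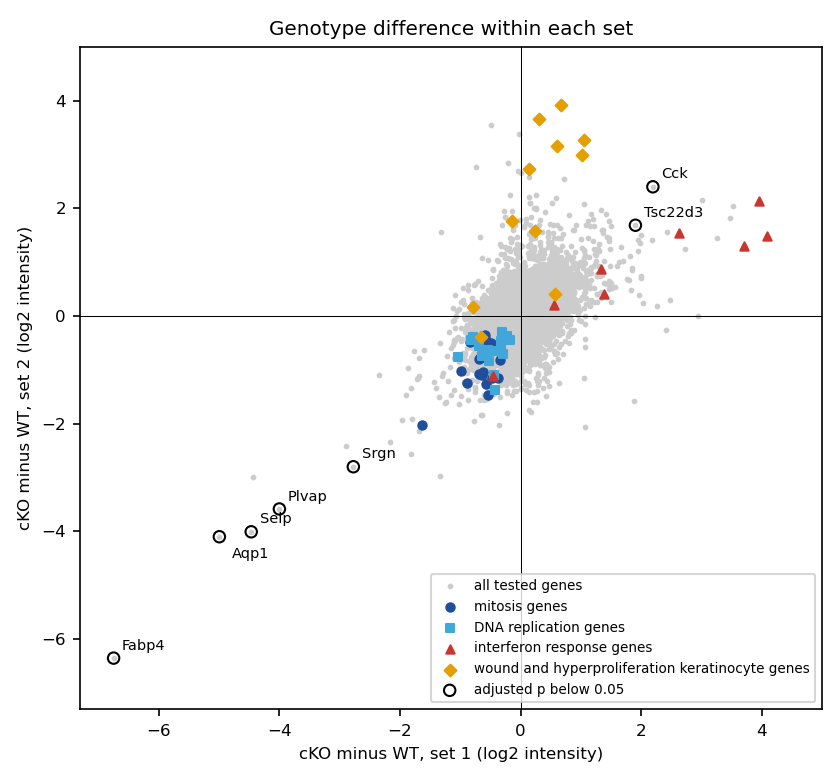
Each point is a gene, with its cKO minus WT difference in log2 intensity in set 1 on the horizontal axis and in set 2 on the vertical axis. Grey points are all 8032 tested genes, coloured points are members of 4 gene lists, and circles mark the 7 genes that passed limma's test. The mitosis and DNA replication genes lie below 0 on both axes.

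The genotype difference was shared between the sets beyond the genes that passed. At an unadjusted p under 0.05, limma gave 1138 genes, where chance alone would give 401.6. Within both sets, 244 genes were at least 1.5-fold higher in cKO and 132 at least 1.5-fold lower, against 13 genes that differed by that much in opposite directions. Across genes, which are not independent replicates, the differences within set 1 and set 2 correlated with Pearson's r = 0.501. With the set as a block in the model, limma called 83 genes (53 higher and 30 lower), including all 7. In simulated data the blocked model, with 1 residual degree of freedom, drew 10.5% false calls on average against 4.66% without the block.

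Other genes had a large difference shared by both sets and did not pass limma's test. Angptl7, an angiopoietin-like protein, differed by 2.78 (adjusted p = 0.094), Ltbp2, a microfibril-associated protein, by 2.58 (0.162), Gdf10, a member of the transforming growth factor β family, by 1.99 (0.131) and Thbs2, a matricellular thrombospondin, by 1.62 (0.162), all with positive values in cKO. Rtp4, Oasl2, Oas1a and Usp18, which respond to interferon, differed by 2.65, 3.04, 2.09 and 2.79. The potassium channel gene Kcnk2 differed by 1.76 and the retinol-metabolising dehydrogenase gene Adh7 by 1.59. In the other direction the cytokine gene Il6 differed by -3.72 (adjusted p = 0.0856), Lrg1 by -2.65, Ctla2a by -2.25, the fatty acid receptor gene Cd36 by -2.19, the peptidase gene Mme by -1.94, the intermediate filament gene Vim by -1.91 and the chemokine-binding receptor gene Ackr1 by -1.85. Both WT arrays lay below the dim limit for Angptl7, Gdf10, Oasl2 and Usp18, and both cKO arrays for Lrg1, Ctla2a and Cd36. Set against that limit, the differences were 2.11, 1.32, 2.02 and 1.87 for the former and -1.92, -1.47 and -1.16 for the latter. With the set as a block, all of these genes except Usp18 (adjusted p = 0.0694) passed limma's test.

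Genes of cell division were lower in cKO as a group. All 25 measured genes of the mitosis list had lower values in cKO within both sets, with a median difference of -0.69, -0.61 in set 1 and -0.77 in set 2. The list was shifted down against other genes by camera (adjusted p = 2.91e-17). All 21 tested genes of the DNA replication list were also lower within both sets, with a median of -0.60, and the list was shifted down as well (camera adjusted p = 1.78e-12). For both lists the adjusted p was 0.617 with an estimated correlation. That test rests on 2 residual degrees of freedom, so it does not tell whether correlated genes made the calls. The kinetochore motor gene Cenpe differed by -1.83, the spindle checkpoint kinase gene Bub1 by -1.07, the proliferation marker Mki67 by -1.0 and the mitotic kinesin gene Kif20a by -1.0. Among replication genes, Mcm5, a subunit of the replicative helicase, differed by -0.90, the licensing factor gene Cdc6 by -0.89, the polymerase gene Pola1 by -0.77 and Uhrf1, which helps to copy DNA methylation, by -0.69. None of these single genes passed limma's test over all genes. Adjusted over the list alone, 24 mitosis genes and 14 replication genes passed, and with the set as a block Cenpe also passed over all genes (adjusted p = 0.0143). Between the cKO set 2 and WT set 1 arrays alone, a comparison added after the data were seen, the median was -0.59 for mitosis and -0.72 for replication genes. Those arrays also differ in set.

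**Figure D2:**
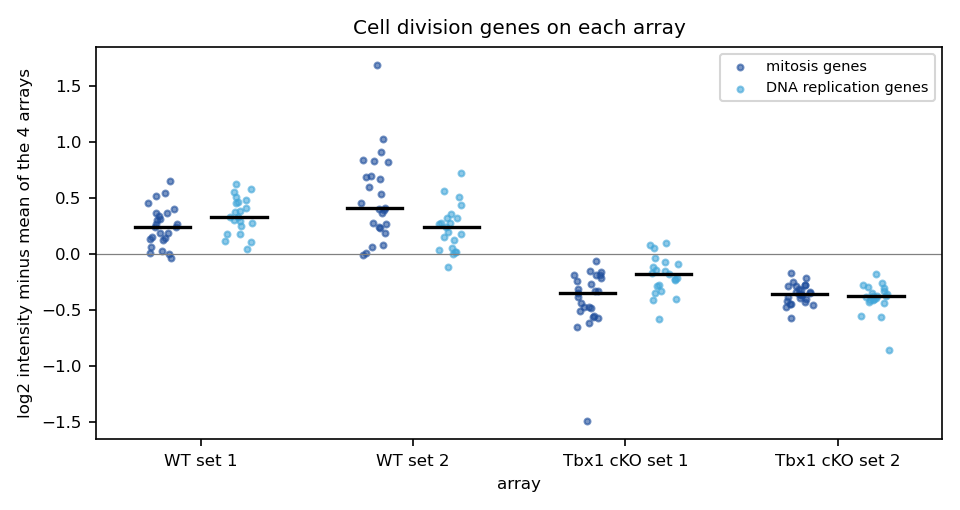
Each point is a gene of the mitosis or DNA replication list on 1 array, as its log2 intensity minus its mean over the 4 arrays, and each black bar is the median of the list. The medians lie above 0 on both WT arrays and below 0 on both cKO arrays.

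The list of cell cycle inhibitors and quiescence genes was not shifted (median 0.20, camera adjusted p = 0.252), although Txnip, Cdkn1a and Foxo3 had differences of 1.38, 0.99 and 0.96 and Rbl1 of -0.58, and 2 of its genes passed adjusted over the list alone. Bulge stem cell genes were shifted up by a small amount, with a median of 0.26 over 19 genes, 0.45 in set 1 and 0.07 in set 2 (camera adjusted p = 0.0364, and adjusted p = 0.617 with an estimated correlation). Foxc1, a transcription factor gene of stem cell quiescence, differed by 0.83, the hemidesmosome collagen gene Col17a1 by 0.81, Wif1 by 0.56 and Runx1 by 0.55, and none passed limma's test over all genes or adjusted over the list alone. A second Runx1 probe set read -0.35. Basal epidermal genes were shifted up with a median of 0.13 over 11 genes (camera adjusted p = 0.0232, and adjusted p = 0.617 with an estimated correlation). Their largest values were 1.13 for Col7a1, 0.81 for Lamb3, 0.74 for Itgb4 and 0.67 for Plec, of which a second probe set read 0.35. No basal gene passed over all genes, and 2 passed adjusted over the list alone. The bulge call was lost without the cKO set 1 array (median 0.22, adjusted p = 0.107) and without the WT set 1 array (0.09, 0.599). The basal epidermal call was lost without the same arrays (adjusted p = 0.0658 and 0.168), although its median was no smaller there, at 0.14 and 0.25, and it was 0.29 without the cKO set 2 array and 0.30 without the WT set 2 array. Of the genes for the sorting markers, Cd34 differed by 0.61 in set 1 and 0.17 in set 2 and Itga6 by 0.50 and -0.02. These were chosen for the sort and not by the rule for named genes.

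Differentiation, wound and interferon genes were higher in cKO, with medians that differed in size between the sets, a difference that was not tested. The interfollicular differentiation list, of genes of the suprabasal epidermis, had a median of 0.96 over 10 genes, 0.19 in set 1 and 1.70 in set 2 (camera adjusted p = 0.00181). The list of wound and hyperproliferation keratinocyte genes had a median of 1.43 over 11 genes, 0.31 in set 1 and 2.72 in set 2 (camera adjusted p = 0.0115). Interferon response genes had a median of 1.6 over 8 genes, 2.01 in set 1 and 1.09 in set 2 (camera adjusted p = 0.0115). Dissociation and immediate early genes, which respond to tissue handling, had a median of 0.24 over 20 genes, 0.00 in set 1 and 0.42 in set 2 (camera adjusted p = 0.0232). For these 4 lists the adjusted p was 0.617 with an estimated correlation. The estimated correlation was 0.71 for differentiation, 0.60 for wound, 0.77 for interferon and 0.47 for immediate early genes, against 0.08 for mitosis genes. A preset of 0.01 makes camera's p too small where genes are correlated this much, so these 4 calls are less sure than that of mitosis genes. The estimates also rest on 2 residual degrees of freedom. The alarmin genes S100a9 and S100a8 differed by 2.29 and 2.17. The cornified envelope genes Sprr2h, Sprr2d, Sprr1b and Sprr1a differed by 2.01, 2.36, 1.88 and 1.33. The keratin genes Krt6b and Krt1 differed by 1.98 and 1.25, and Ifit1 by 2.50. Several of these means rest mostly on set 2. Within set 1 and set 2, S100a9 differed by 0.66 and 3.91, Sprr1b by 0.60 and 3.17 and Sprr1a by 0.01 and 2.66. Krt6b differed by 0.31 and 3.65 and Krt1 by 0.26 and 2.25. Krt6b read 7.80 on the WT set 2 array and 10.96 to 11.45 on the other arrays. S100a8 (1.06 and 3.28) and Sprr2h also differed more in set 2. Sprr2d (3.26 and 1.45) and Ifit1 (3.71 and 1.29) differed more in set 1. Both WT arrays lay below the dim limit for S100a8, Sprr2d and Ifit1, which set against that limit differed by 1.72, 2.03 and 2.08. Without the filter on dim genes the list medians were smaller, at 0.88 over 14 differentiation, 0.81 over 15 wound and 1.10 over 13 interferon genes. Dusp1, Klf4, Fosb and Ier3 of the immediate early list had differences of 0.87, 0.71, 0.51 and 0.45. No single gene of these lists passed limma's test over all genes. Adjusted over the list alone, 6 interferon genes were higher and 1 lower, and no gene of the other 3 lists passed; with the set as a block, Oasl2 and Oas1a passed over all genes (adjusted p = 0.0238 for both). The interferon call was lost without the WT set 1 array (median 1.96, camera adjusted p = 0.171) and without the WT set 2 array (1.29, 0.0866), with the median still of similar size, and kept without the cKO set 1 array, where the median was 0.85. The differentiation call was lost without the WT set 2 array (median 0.30, adjusted p = 0.0866), and the immediate early call without the cKO set 2 array (0.17, 0.0981) and without the WT set 2 array (0.10, 0.438). The wound call was kept without the WT set 2 array with a smaller median (0.44, 0.0398). Without the WT set 1 array the medians were larger, at 2.04 for differentiation, 2.39 for wound and 0.36 for immediate early genes.

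The WT set 2 array stood apart in Xist, Malat1 and Neat1, long noncoding RNAs of the nucleus, and it enters every set 2 value above. Xist read 13.37 there and 11.96 to 12.30 on the other arrays, Malat1 12.35 against 9.80 to 10.56, and Neat1 9.08 against 7.46 to 8.51. The cKO set 1 array, which enters every set 1 value, had weak signal at the 5′ end of control transcripts. The 3′ minus 5′ difference of the added Dap control was 2.95 there and 1.74 to 1.82 on the other arrays. Between the arrays outside both of these, cKO set 2 and WT set 1, the median difference was 0.45 for differentiation genes, 0.49 for wound genes, 0.57 for interferon genes, 0.14 for immediate early genes, 0.28 for bulge genes and 0.15 for basal epidermal genes. These arrays belong to different sets, so the values mix genotype with set. Over all arrays the set 2 minus set 1 medians were -0.75, -0.20, -1.09, -0.20, 0.01 and -0.08 in the same order.

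None of the signalling lists was shifted. For bone morphogenetic protein (BMP) pathway components the median was 0.10 (camera adjusted p = 0.436) and for BMP target genes 0.11 (0.300). The ligand gene Bmp2 differed by 1.48, the antagonist genes Fst and Grem1 by 0.74 and -0.55, and the receptor gene Acvr2a by 0.37. Of the targets, Id2 differed by 1.19, Id1 by 1.01, Id3 by 0.70 and Msx2 by -0.57. Transforming growth factor β genes had a median of -0.07 and a mean of 0.09 (camera adjusted p = 0.814), with 1.58 for Ccn2. Of these genes, 5 were higher within both sets and 5 lower. WNT targets had a median of 0.28 (camera adjusted p = 0.242), with 0.95 for Myc and 0.78 for Wnt10a, and 6 were higher within both sets and 3 lower. The Hedgehog list had a median of -0.02 (camera adjusted p = 0.755), with 0.84 for the coreceptor gene Boc, 0.53 for Gas1, -0.78 for the receptor gene Ptch1 and -0.53 for the effector gene Gli1. Growth factor feedback genes of the FGF and ERK list had a median of 0.21 (camera adjusted p = 0.293), with 1.20 for Spry1. In that list 6 were higher within both sets and 2 lower. The Notch list had a median of 0.16 (camera adjusted p = 0.212), with 1.01 for Dll1 and 0.75 for Notch3, and it was called with the set as a block (camera adjusted p = 0.0484) and without the cKO set 2 array (median 0.36, adjusted p = 0.0159). Second probe sets of Id2 and Ptch1 read 0.52 and -0.17. None of these genes passed limma's test over all genes. Adjusted over the list alone, 1 gene passed in each of the BMP component, BMP target and transforming growth factor β lists, 2 in the WNT list, 4 in the Hedgehog list (2 higher and 2 lower) and 0 in the FGF and Notch lists. In contrast, with the set as a block Bmp2 (adjusted p = 0.021), Id2 (0.0304), Ccn2 (0.0297), Spry1 (0.0304) and Col7a1 of the basal list (0.0403) did.

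Markers of endothelial cells, which the sort was not meant to include, were lower in cKO along with the genes that fell. Only 3 of the 13 endothelial and mural markers with a probe set were bright enough to be tested, too few for a list test with the filter on dim genes. Without the filter, camera called the list lower, with a median of -0.51 over the 13 genes (adjusted p = 1.69e-09), whereas the adjusted p was 0.323 with an estimated correlation and 0.0951 by fry. Of all 13, 10 were lower in cKO within both sets, 6 of these at least 1.5-fold lower within both, and 2 were higher within both. Vwf, a clotting factor gene of endothelium, read 7.24 and 6.30 in WT and 2.96 and 3.18 in cKO, Emcn 5.44 and 5.64 against 3.57 and 3.60, and Cdh5 5.70 and 5.18 against 3.90 and 3.86. These 3 genes were chosen after their values were seen.

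**Figure D3:**
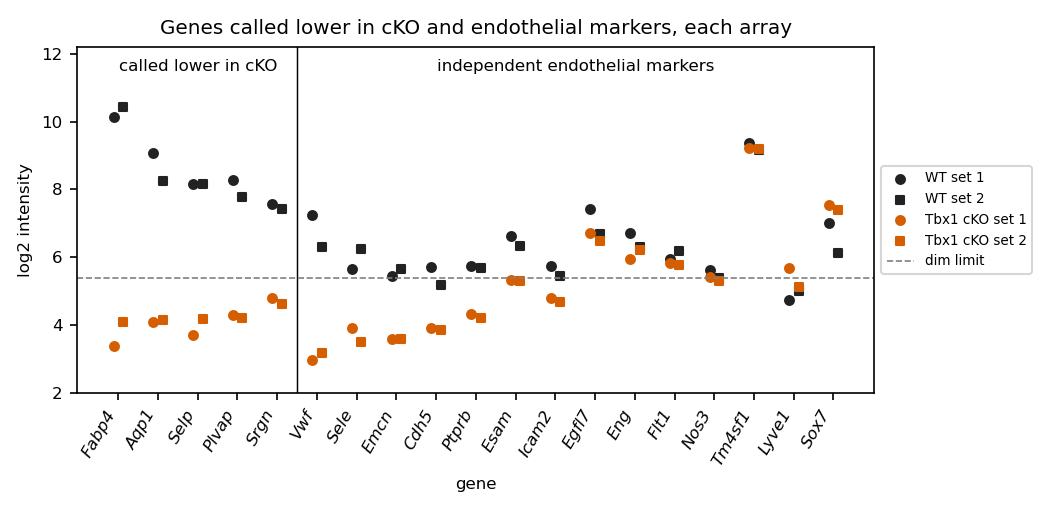
Points give the log2 intensity of each array for the 5 genes called lower in cKO, left of the line, and for the 14 endothelial markers of a separate list that reach the dim limit on some array, right of it. The dashed line is the limit for dim genes, 5.40. Fabp4, Aqp1, Selp, Plvap and Srgn lie above the limit on both WT arrays and below it on both cKO arrays.

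Beyond the bulge, basal epidermal and differentiation lists above, no cell type list tested with the filter on dim genes was shifted. The median was -0.07 for dermal fibroblast markers, with a mean of 0.18 (camera adjusted p = 0.814), and their largest members went both ways, with -1.91 for Vim, 1.46 for Thy1, 1.35 for Mmp2 and 0.98 for Sparc. Adjusted over the list alone, 3 fibroblast markers were higher and 1 lower. Vim (adjusted p = 0.0141) and Thy1 (0.021) passed limma's test with the set as a block. Immune cell markers had a median of 0.32 (camera adjusted p = 0.234), melanocyte markers 0.34 (0.210, but 0.0232 with a median of 0.41 without the cKO set 1 array), sebaceous gland genes 0.31 (0.233), hair germ and matrix genes 0.16 (0.690), and hair shaft and root sheath keratins 0.27 (0.234). Housekeeping genes had a median of -0.04 (camera adjusted p = 0.488). Dermal papilla markers and muscle, fat and blood markers had 2 and 4 members bright enough to be tested. Over all their members with a probe set, the medians within set 1 and set 2 were 0.05 and 0.09 for papilla markers and 0.12 and 0.10 for muscle, fat and blood markers, a list that holds Fabp4, and without the filter camera called neither list (adjusted p = 0.930 and 0.867). Y-linked genes read at most 3.47 on any array, near the lowest intensities, on samples labelled female.

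The comparison of set 2 with set 1 asked how the samples called activated differed from those called quiescent. limma called no gene of 8032. At an unadjusted p under 0.05 there were 230 genes, below the 401.6 that chance would give, in a fit that leaves the genotype difference among the residuals, and the lowest adjusted p was 0.274. With genotype as a block there were 691 genes at an unadjusted p under 0.05, and 1 gene passed, Ehd3, a gene of endosome recycling, at -2.66 (adjusted p = 0.0204), with both set 2 arrays below the dim limit. Within both genotypes, 46 genes were at least 1.5-fold higher in set 2 and 65 at least 1.5-fold lower, against 40 that differed by that much in opposite directions, and the differences in cKO and WT correlated across genes with r = 0.192. Among the largest shared differences, the ubiquitin ligase gene Nedd4 differed by 1.53, the chromatin remodeller gene Atrx by 1.54, Plscr1 by 1.65, Mpp5 by 1.39, Washc4 by 1.36, Cenpe by 1.36, Akap9 by 1.32, Cntrl by 1.13, Irak1bp1 by 1.11, Cfap97 by 1.07, Zc3h15 by 1.05 and Dcun1d1 by 0.97. Other bright probe sets differed less, with 0.32 and 0.54 for Nedd4, 0.47 and 0.61 for Mpp5, 0.51 for Zc3h15 and 0.63 and 0.30 for Dcun1d1. In the other direction, the cornified envelope gene Lor differed by -2.67, Lce1a2 by -2.19, Lce1b by -2.11, Lce1a1 by -1.93, Lce1f by -1.85 and Lce1i by -1.52. Lce1 genes are close copies of each other, and their probe sets may not tell them apart. Mcam differed by -1.68, Vill by -1.64, Bckdhb by -1.59, Wfdc21 by -1.58 and 2310050C09Rik by -1.55. For Vill and 2310050C09Rik both set 2 arrays lay below the dim limit, and set against it they differed by -1.05 and -0.86.

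Of the 23 lists tested between the sets, 1 was shifted. Interfollicular differentiation genes were lower in set 2, with a median of -0.75 (camera adjusted p = 0.0422, and adjusted p = 0.901 with an estimated correlation). The median was 0.02 in cKO and -1.62 in WT, and the call was lost after a second quantile normalisation (median -0.74, adjusted p = 0.0514), after centring each array (-0.77, 0.0677), without the cKO set 1 array (median -0.64, adjusted p = 0.134) and without the WT set 2 array (0.15, 0.311). camera called 5 lists without the cKO set 2 array and 4 without any other single array. Mitosis and DNA replication genes had medians of 0.01 and -0.14 (camera adjusted p = 0.158 and 0.291). With genotype as a block, camera called 3 lists lower in set 2, differentiation (adjusted p = 0.000369), interferon response (median -1.09, adjusted p = 0.000161) and Notch (-0.40, 0.011), and 1 list higher, mitosis genes (mean 0.15, adjusted p = 0.0174). With single arrays left out, the mitosis median was 0.38 without the WT set 1 array (camera adjusted p = 2.95e-06), 0.41 without the cKO set 2 array (5.27e-07), -0.21 without the cKO set 1 array (0.134) and -0.30 without the WT set 2 array (0.00161). The interferon median ran from -2.10 without the WT set 1 array to 0.08 without the cKO set 1 array, and the Notch median from -0.49 without the cKO set 2 array to -0.23 without the cKO set 1 array. The replication median was 0.13 (0.141), 0.16 (0.0918), -0.45 (4.56e-05) and -0.42 (5.43e-08) without the WT set 1, cKO set 2, cKO set 1 and WT set 2 arrays. A fit without 1 array sets unequal numbers of cKO and WT arrays against each other, so these values also hold part of the genotype difference.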

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

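The tests of weak labelling, of dividing cells of another type and of more division in set 2, and the other filters on endothelial markers, were chosen only after the results were seen. The tests of endothelial cells and of outlying arrays were written before their values were computed. The pair of arrays used in the test of outlying arrays was itself chosen after the data were seen.

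Several of the 5 genes that fell in cKO are known from endothelium. A candidate explanation is that the WT sorts held endothelial cells, which carry CD34 and integrin α6 and would be removed by the YFP gate if they lack YFP. Over 14 endothelial markers at or above the dim limit on some array, none of them among the called genes, the median cKO minus WT difference was -0.66 (bootstrap interval -1.56 to -0.15), with 11 lower within both sets and 2 higher within both, Sox7 by 0.54 and 1.28 and Lyve1 by 0.95 and 0.14. This median decides nothing by its size, because the 7 markers at least 1.5-fold lower within both sets met the limit through the WT arrays alone, with both cKO arrays below it. Over all 28 markers with a probe set the median was -0.45 (interval -0.87 to -0.22), with 20 lower within both sets and 3 higher. Of the 28, 11 were at least 1.5-fold lower within both sets and 0 higher by that much, and all 11 lay below the limit on both cKO arrays. The median was -0.26 over the 5 above the limit on all 4 arrays (interval -0.47 to 0.91). The most abundant, Tm4sf1 at 9.15 to 9.37, barely differed, and 5 of the 14 are also in the fixed endothelial list. Without a filter more markers were lower than higher, which endothelial cells in the WT sorts would give. Lower levels of these transcripts in the sorted stem cells themselves would give the same values. Such endothelial cells therefore cannot be told apart from other explanations. The markers that differ most lie near the lowest intensities in cKO. The brighter ones go both ways but do not weigh against such cells. If the cKO sorts held none, a marker carried by endothelial cells alone would fail the limit on the cKO arrays. Weak 5′ labelling of the cKO set 1 array cannot account for the values in set 2, which does not use it. The 5 genes had a median difference of -4.01 there. That value is no independent test, because a gene low on the cKO set 1 array alone would hardly pass limma with 2 arrays per group. A direct effect of Tbx1 loss, or fewer vessels near the cKO follicles, stays open and untested.

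Mitosis and DNA replication genes were lower in cKO. If one outlying array in each set were the cause, the arrays that do not stand apart would differ little, but cKO set 2 minus WT set 1 gave a median of -0.65 over 46 genes (interval -0.72 to -0.58), with all 46 negative. Those arrays also differ in set, and the median set 2 minus set 1 difference of the 46 genes was -0.045. Dividing cells of another type in the WT sorts would dilute keratinocyte genes there. The median of 30 basal epidermal and bulge genes was 0.25 (interval 0.09 to 0.50), neither below 0 nor as large as the shift of the division genes, so this cannot be told apart from slower division of the stem cells, because the share of such cells is unknown. Lower division in Tbx1-deficient stem cells is therefore a hypothesis only.

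Set 2 was described as activated and set 1 as quiescent. If set 2 held more dividing cells, division genes would be higher there. Their median set 2 minus set 1 difference was -0.045 over 46 mitosis and DNA replication genes (interval -0.13 to 0.04), with 0.01 in WT and -0.10 in cKO, which shows no shared rise of 1.5-fold. The lists went apart, with a mean of 0.15 for mitosis genes, called higher by camera with genotype as a block (adjusted p = 0.0174, and 0.158 without the block), and -0.16 for replication genes (0.141 and 0.291). With single arrays left out the mitosis median ran from -0.30 without the WT set 2 array to 0.41 without the cKO set 2 array. A small rise in dividing cells cannot be told apart from none, with 1 array per set and genotype. A difference of timing that leaves division genes equal stays open, as does a description that does not apply to these samples.

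Medians of 9 lists differed in sign between cKO and WT in the set comparison, and these differences were not tested. The WT value minus the cKO value was 0.24 for bulge stem cell genes, -0.12 for BMP targets, 0.18 for mitosis genes, -0.50 for hair germ genes, -0.38 for hair shaft keratins, -1.64 for interfollicular differentiation genes, -1.36 for wound genes, -0.40 for immediate early genes and 0.39 for fibroblast markers. In the genotype comparison the set 2 value minus the set 1 value was -0.080 for BMP components, -0.047 for transforming growth factor β genes and 0.10 for Hedgehog genes, and for single genes -0.77 for Acvr2a and 1.54 for Fosb, each with opposite signs in the sets and also not tested.

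Control probe sets, which enter no comparison, set the cKO set 1 array apart. Its 3′ minus 5′ difference was 2.95 for the Dap control and 2.79 for the Thr control, against 1.74 to 1.82 and 1.70 to 1.80 on the other arrays. For Gapdh it was 0.68 there and 0.24 to 0.34 elsewhere.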

How the results depend on the processing

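Of 1909 values under alternatives, 1771 were counted as kept, while 67 passed and 27 failed the threshold under the alternative alone. Kept values held their direction and their side of the threshold, or stayed within 1.5 times the count or 1 SD of the value. A value that changed direction was also counted as kept where neither it nor the main value passed the threshold. The comparison of 2 arrays and 3 other filters on the separate endothelial markers were chosen after seeing the data, and those filters gave medians of -0.45 (none), -0.26 (mean level) and -0.26 (every array) against -0.66. For the genotype, limma called 0 genes at the percentile 60 filter (816 at an unadjusted p under 0.05), because 6 of the 7 are dimmer on average than that filter and Tsc22d3 had an adjusted p of 0.104, 8 without a filter (6 of the 7, without Tsc22d3), 6 with the mean of probe sets (5 of the 7, without Tsc22d3, and without Fabp4, whose mean was dim), 28 with a variance trend and robust fitting, 83 with the set as a replicate block, 39 at a threshold of 0.10, and 2 to 16 with each array left out. The fewest came without the WT set 2 array and the most without the cKO set 2 array. The 28, 83 and 39 included the same 7 genes. Genes that differed the same way in both sets were 91 at 2-fold, 228 at the percentile 60 filter and 572 with each probe set on its own (12528 probe sets tested). camera called 9 of 26 lists without a filter, the same 8 and endothelial markers, 7 of 19 at the percentile 60 filter, where interferon genes had 1 member left and were not tested, 5 to 8 of 23 lists with each array left out, 0 with an estimated correlation and 0 by fry (1 and 2 lists at an unadjusted p under 0.05). Mitosis and DNA replication lists were called under every other alternative that camera was run with, with medians from -0.78 to -0.57 and -0.70 to -0.48. Tbx1 differed by -1.56 to -0.91 with each array left out and never passed. Between the sets, limma called 1 gene with genotype as a block and 0 under the other alternatives (107 to 842 at an unadjusted p under 0.05 where an array was left out). Shared differences were 25 at 2-fold, 64 at the percentile 60 filter and 256 with each probe set on its own. camera called 4 lists without a filter and 4 with genotype as a block, 0 after quantile normalisation and 0 after centring, where the differentiation call was lost (adjusted p = 0.0514 and 0.0677), 0 with an estimated correlation (0 lists at an unadjusted p under 0.05), and 4 to 5 with each array left out. Leaving out the WT set 2 array reversed the direction in camera of 3 lists where the main or the alternative value passed the threshold. Their medians became -0.30 for mitosis (range over arrays -0.30 to 0.41), 0.15 for differentiation (-1.94 to 0.15) and 0.35 for wound genes (-1.22 to 0.35). Lists that changed sign where neither value passed are not in this count. Apart from the values given with a reason, the cause was not tested. The block changed no call other than those given in the report and of unnamed genes within the 83. Signal near the lowest intensities limits the folds of Fabp4, Aqp1, Selp, Plvap, Srgn and Cck, and of 10 other genes named between genotypes and 3 between sets.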

Other observations

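The test of glucocorticoid-responsive genes was prompted by Tsc22d3 and Txnip and used other genes, whose values had not been seen when the test was written. The test of the Tbx1 neighbourhood was also written before its values were computed.

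Genes known to respond to glucocorticoids were higher in cKO as a group. Of 22 listed genes without Tsc22d3, Txnip and Dusp1, 15 were tested, and 12 were higher in cKO within both sets and 1 lower within both. The median difference was 0.32 (bootstrap interval over genes 0.28 to 0.52), 0.33 in set 1, 0.39 in set 2 and 0.43 between the cKO set 2 and WT set 1 arrays, which also differ in set. Zbtb16 differed by 0.88, Klf9 by 0.83, Errfi1 by 0.65, Cebpd by 0.52 and Per1 by 0.41, whereas Fkbp5 and Sgk1, common targets, differed by 0.09 and 0.06 and Ddit4 by -0.21. camera gave p = 0.000616 with the preset correlation and p = 0.0673 with an estimated correlation, for this list alone and not adjusted for the fixed lists. A stronger glucocorticoid response in cKO cells may be one hypothesis for this shift. Fkbp5 and Sgk1 differing little leaves it weak, and some of these genes also respond to other kinds of stress.

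A linked or local effect around the Tbx1 locus, such as flanking sequence carried along with the modified allele, was tested through the 20 tested genes nearest to Tbx1 on its chromosome. Of these, 0 differed at least 1.5-fold the same way in both sets, against 375 of 8011 other genes (4.68%), so the one-sided Fisher exact p was 1. The data give no sign of such an effect, although 20 genes at that rate would be likely to hold about 1 in any case.

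Between arrays over all probe sets, the highest correlation was between the cKO arrays (r = 0.993), followed by cKO set 2 with WT set 1 (r = 0.991). The lowest was between cKO set 1 and WT set 2 (r = 0.980). The number of genes differing at least 1.5-fold was 399 between the cKO arrays and 1032 between the WT arrays.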
